A study of Mus musculus with 22 samples.

How the data were processed

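The series profiled nuclear RNA of the mouse lumbar dorsal horn by RNA sequencing. Per the labels' protocols, tissue of both sides was dissected from pDyn-Sun1-GFP mice, nuclei were released by homogenization and filtering, and flow sorting gave a GFP+ and a GFP- sample of 5000 nuclei from each animal. Libraries were made with the NuGEN SoLo system and 15 cycles of amplification and were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The labels name 22 samples from 11 animals: 4 animals at P7, 3 at P21 and 4 at P80.

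The submitters' processing notes name Trim Galore, cutadapt, STAR, HTSeq and DESeq2, without versions or the step each was used for. The genome build, the annotation and the settings of the aligner and counter are not given in the sources used here, and no coordinates are printed. Per the file headers, the per-library columns hold a normalized expression value. These deposited values were treated as a signal: each library's values were whole multiples of 1 step, within a tolerance of 0.01, for 100% of values, so that they are gene counts that the authors divided by 1 size factor per library, and whole reads could be recovered. The value of 1 read lay between 0.547 and 1.31. The deposited log2 fold changes (GFP over CONTROL) with their standard errors, and the deposited p-values and adjusted p-values, were made by the authors with a Wald test, per the file headers. A further deposited table gives p-values of an across-age test of GFP+ nuclei and cluster letters, whose methods are not given in the sources used here. The authors' fold changes, p-values and cluster letters were used only for comparison.

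Columns carry library codes (ES1 to ES24) that the labels do not repeat. Age was taken from the authors' per-age sheet that holds a column, and population from the across-age table, whose columns are GFP+ nuclei. The resulting groups had the numbers of libraries that the labels give. The signs of the fold changes recomputed with this grouping were those of the authors' called genes in 8705 of 8707 genes over all ages, 4569 of 4569 at P7, 2877 of 2877 at P21 and 4347 of 4347 at P80. The sexes in the labels could be compared with Xist and 4 Y-linked genes only as counts per group. Xist exceeded the sum of the Y-linked genes in as many libraries as the labels give females, except in the P21 GFP- group (2 against 1). There the library ES16 held both kinds of transcript, so it does not clearly contradict the labels. Its Xist was 9.96% and its Y-linked sum 63.8% of the mean of the libraries high for each. The columns do not say which GFP+ and GFP- libraries came from the same animal, so the animal could not enter a fit, and the labels' sexes could not be joined to single columns. Sex was not assigned to libraries from their values for use in a fit.

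The design was fixed before the data were examined, with 1 branch for counts and 1 for normalized values, and the second applied. Genes with a value of at least 10 in at least 3 libraries were kept, 18614 of 21363. Of the 21363 genes, 16640 are coding, per the authors' table. Gene names are the authors' symbols, and 20984 identifiers matched a current mouse symbol. A limma fit (version 3.58.1, R 4.3.3, trend and robust options) of 6 group means to log2(value + 1) used all 22 libraries, which share 1 estimate of the spread. Contrasts were GFP+ minus GFP- averaged over the 3 ages and at each age, the 3 age differences within GFP+ nuclei, and the interaction of age and population with 2 degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tests are two-sided.

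Gene lists were fixed together with the design: pan-neuronal, inhibitory neuron, excitatory neuron, neuropeptides of inhibitory and of excitatory dorsal horn neurons, motor neuron, opioid system, peptide and monoamine receptors, ionotropic and metabotropic glutamate receptors, GABA-A and glycine receptors with chloride transporters, potassium channels, sodium and calcium channels with HCN, presynaptic release machinery, immature neuron, axon guidance, perinatal growth and imprinted genes, cell cycle, immediate early genes, perineuronal net and matrix, oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, endothelial and mural, meningeal fibroblast, ependymal, Schwann cell, red blood cell, mitochondrially encoded transcripts and cytosolic ribosomal proteins. These 31 lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. A primary sensory neuron list had fewer than 3 tested genes (Calca and Avil) and could not be tested. List scores are means of log2(value + 1) per library. Differences of scores between populations were tested by exact permutation within each age.

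Genes named in the text were taken by a rule fixed with the design: Pdyn, then the 10 highest and 10 lowest fold changes averaged over ages and from P7 to P80, the 5 highest and 5 lowest in the other comparisons, the 10 smallest p of the interaction, and up to 4 members of each list with the smallest p. The fold-ranked genes had to pass the test, have at least median expression and a gene symbol that is not a clone or microRNA name. Some genes taken by this rule are not reported here. The rule also asked for the same direction in every animal. Since animals could not be matched, non-overlap of the GFP+ and GFP- libraries at each age concerned took its place. Hemoglobin genes have near-identical copies, and the handling of strand in counting is not given in the sources used here, so values of near-identical, overlapping and antisense genes are uncertain.

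Depth was 4244987 to 10849169 reads per library, the nuclear noncoding RNA gene Malat1 took between 4.01% and 11.5% of them, and a count of 3 reads corresponded to a value between 1.64 and 3.92. The analysis was tested on simulated data with 200 changed genes drawn from the real means. Genes were drawn independently, each from its mean over all libraries, so shifts that many genes share within a library were absent. The p that passes adjustment depends on how many genes change. These shares may therefore not hold in comparisons that called far more than 200 genes. In the comparison averaged over ages (18179 genes) 35.8% of genes changed 1.5-fold, 59.7% of 2-fold and 90.9% of 4-fold changes were recovered. The 4-fold and 2-fold shares were 71.2% and 34.3% at P7 (18212 genes), 69.7% and 29.9% at P21 (18241 genes), 74.2% and 35.8% at P80 (18222 genes), 75.8% and 28.4% from P7 to P21 (18219 genes), 77.3% and 25.4% from P21 to P80 (18219 genes), 78.8% and 28.4% from P7 to P80 (18222 genes) and 53.0% and 11.9% for the interaction (18227 genes). False calls were 5 of 129 averaged over ages, 1 of 79 at P7, 6 of 76 at P21, 2 of 81 at P80, 5 of 80 from P7 to P21, 1 of 71 from P21 to P80, 2 of 80 from P7 to P80 and 1 of 44 for the interaction.

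Alternatives were pseudocounts of 0.5 and 5, TMM rescaling, no filter, a 2-fold floor, fits of 1 age or of GFP+ libraries alone, DESeq2 1.42.0 and edgeR 4.0.16 quasi-likelihood tests on recovered reads, leaving out each library, and dropping the P21 GFP- library ES16. Other splits of the libraries into groups of the same sizes were also fitted, at most 100 per comparison. Reads are amplified without molecular identifiers in the sources used here, so counting precision is not that of molecules.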

Results

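Nuclear RNA from the lumbar spinal dorsal horn was sequenced in mice of the pDyn-Sun1-GFP strain. Per the labels, this strain makes a GFP-tagged protein of the nuclear envelope from the promoter of prodynorphin, the precursor of dynorphin opioid peptides, and the GFP+ nuclei are termed pDyn-lineage. Whether GFP marks past or only present use of that promoter is not given in the sources used here. Sorting gave a GFP+ sample and a GFP- sample of the remaining nuclei from each of 11 animals, 4 at postnatal day 7 (P7), 3 at P21 and 4 at P80, with 5000 nuclei per sample. The 22 libraries held between 4244987 and 10849169 reads counted to genes, with a median of 5359703, and between 20014 and 21027 genes with at least 1 read. Values are read counts divided by 1 size factor per library, and fold changes are on the log2(value + 1) scale with their standard error from limma, which understates the change of genes near the floor. Of 21363 genes, 18614 reached a value of 10 in at least 3 libraries and were tested, and unless another test is named every adjusted p is from limma, two-sided, with Benjamini-Hochberg adjustment.

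Pdyn itself separated the 2 populations in every library. GFP+ nuclei had a mean normalized count of 511 ± 75.2 (SD, n = 11; range 405 to 663, or 357 to 805 reads), against 7.42 ± 5.11 (SD, n = 11; range 0 to 15.7, or 0 to 21 reads) in GFP- nuclei. The GFP+ means were 587 ± 58.2 at P7 (SD, n = 4), 454 ± 59.9 at P21 (n = 3) and 476 ± 23.2 at P80 (n = 4). The Pdyn difference averaged over ages was 6.25 ± 0.37 on the log2 scale (adjusted p = 4.49e-11), and it was 6.82 ± 0.61 at P7, 5.91 ± 0.71 at P21 and 6.02 ± 0.61 at P80.

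**Figure D1:**
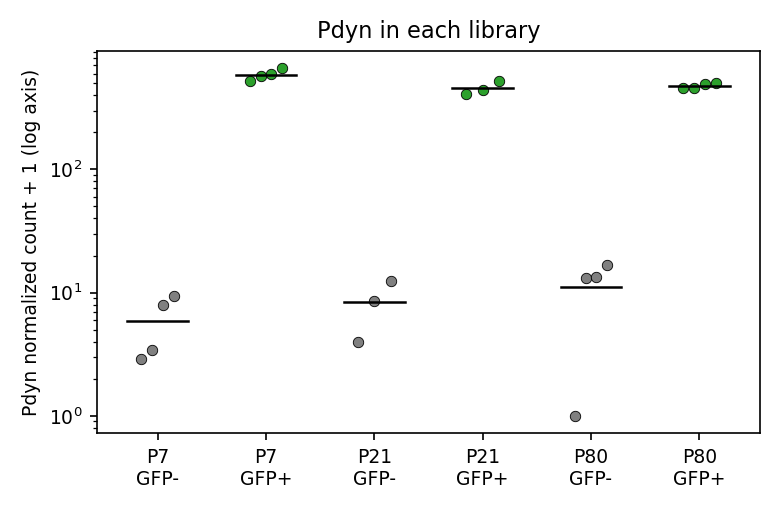
Normalized Pdyn count plus 1 in each library on a log axis, by age and population, with a line at each group mean. The 11 GFP+ libraries lie between 405 and 663 and the 11 GFP- libraries between 0 and 15.7 before the 1 is added.

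The first comparison asked how the transcriptome of pDyn-lineage nuclei differs from that of the other dorsal horn nuclei, averaged over the 3 ages. With the preset correlation limma's camera called 21 of 31 lists, 12 higher and 9 lower, and with an estimated correlation 0, although 8 had an unadjusted p under 0.05. The lists called higher with the preset correlation included those of inhibitory neurons, inhibitory peptides, synapses and ion channels, and the lists called lower included those of oligodendrocytes, astrocytes, microglia and vessels. In this and the later comparisons, fold changes are ranked among genes of at least median expression that passed, whose libraries did not overlap and whose symbol is not a clone or microRNA name. The highest fold changes were those of Robo3 and Sstr2, each with n = 11 per population. Robo3, which encodes an axon guidance receptor of commissural neurons, was higher by 4.39 ± 0.21 (adjusted p = 1.07e-12), and the somatostatin receptor gene Sstr2 by 4.06 ± 0.14 (adjusted p = 3.93e-15). Pnoc, the gene of the nociceptin precursor, was higher by 3.93 ± 0.25 (adjusted p = 7.76e-11). Col6a6, a collagen gene (3.91 ± 0.33), Nos1, which encodes neuronal nitric oxide synthase (3.47 ± 0.17), and Rasgrp1 (3.24 ± 0.18) followed. Skor1 (3.16 ± 0.16), the transcription factor gene Pax8 (3.12 ± 0.23), Abi3bp (3.03 ± 0.18) and the cation channel gene Trpc4 (2.97 ± 0.19) came next. The lowest fold changes were those of Cspg4 at -3.80 ± 0.27, Pdgfra at -3.74 ± 0.19, Gjc3 at -3.72 ± 0.23, Plxnb3 at -3.65 ± 0.23 and Tmem63a at -3.60 ± 0.20. They were followed by Aspa at -3.56 ± 0.23, Cdh19 at -3.54 ± 0.21, Sec14l5 at -3.51 ± 0.24, Sox10 at -3.50 ± 0.22 and Olig2 at -3.44 ± 0.23. Pdgfra, Cspg4, Sox10 and Olig2 are known from the oligodendrocyte lineage.

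Of 12 inhibitory neuron genes, 9 were higher and 1 lower, with the same counts adjusted over the list alone and a median of 1.52 (camera adjusted p = 1.09e-05, adjusted p = 0.216 with an estimated correlation). Gad1 and Gad2, which make GABA, were higher by 1.82 ± 0.16 and 1.91 ± 0.17, and the transcription factor gene Lhx5 by 2.03 ± 0.20. Of 12 neuropeptide and marker genes of inhibitory dorsal horn neurons, 9 were higher and 2 lower, again with the same counts adjusted over the list alone. Their median was 1.18 (camera adjusted p = 0.000277, adjusted p = 0.216 with an estimated correlation). Among them the galanin gene Gal was higher by 5.01 ± 0.28 and the enkephalin precursor gene Penk by 1.97 ± 0.13. The list also holds Sst and Calb2, and whether its members are confined to inhibitory neurons was not tested. All 7 measured opioid system genes were higher, over all genes and adjusted over the list alone. Their median was 1.63 (camera adjusted p = 5.23e-06, adjusted p = 0.183 with an estimated correlation). Pdyn is 1 of these 7 genes, and its rise was built into the sort, which rests on its promoter. Penk and Pnoc are also counted among the inhibitory peptide genes. The list was not tested without Pdyn. Oprk1, the gene of the dynorphin receptor, was higher by 1.63 ± 0.20.

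Genes of excitatory neurons did not move together. Of 10 excitatory neuron genes, 3 were higher and 5 lower, with the same counts adjusted over the list alone. Their median was -0.52 (camera adjusted p = 0.499). Tacr3, the neurokinin B receptor, was higher by 2.58 ± 0.12, whereas the transcription factor genes Maf and Ebf2 were lower, at -1.45 ± 0.10 and -1.33 ± 0.13, and Nmur2 at -1.28 ± 0.15. Of 9 neuropeptide genes of excitatory dorsal horn neurons, 4 were lower and 5 did not pass, the same adjusted over the list alone. Their median was -0.51 (camera adjusted p = 0.0469, adjusted p = 0.32 with an estimated correlation), and the list was not called without any 1 of the libraries ES6, ES7, ES11, ES14, ES18, ES21, ES23 and ES24 (adjusted p between 0.0506 and 0.106). The 4 were Nmu at -2.92 ± 0.24, Nts at -2.58 ± 0.22, Grp at -1.80 ± 0.37 and Cck at -1.35 ± 0.17.

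In the pan-neuronal list 13 of 14 genes were higher, also adjusted over the list alone. Their median was 0.77 (camera adjusted p = 3.02e-06, adjusted p = 0.241 with an estimated correlation). The pan-neuronal score varied among GFP- libraries: it was 9.16 in ES12, 9.34 in ES16 and 9.18 in ES8, against 9.83 to 10.25 in the other 8. ES12 and ES8 also had the highest oligodendrocyte scores, 11.84 and 11.88, where the other GFP- libraries had 9.56 to 10.93. Celf4 was at 1.21 ± 0.13 and Syt1, the gene of a calcium sensor of vesicle release, at 1.32 ± 0.16. In the presynaptic release list, which shares 4 genes with the pan-neuronal one, 19 of 22 genes were higher, also adjusted over the list alone. Their median was 0.69 (camera adjusted p = 3.61e-08, adjusted p = 0.216 with an estimated correlation). Of 24 sodium, calcium and HCN channel genes 21 were higher and 2 lower, with the same counts adjusted over the list alone. Their median was 0.84 (camera adjusted p = 3.37e-07, adjusted p = 0.279 with an estimated correlation). Of 24 potassium channel genes 14 were higher and 3 lower, or 15 and 3 adjusted over the list alone. Their median was 0.69 (camera adjusted p = 5.3e-05, adjusted p = 0.32 with an estimated correlation). Kcnt2 was at 2.60 ± 0.13 and Kcnc2 at 1.91 ± 0.13. Ionotropic glutamate receptor genes were higher in 13 of 18 and lower in 2, the same adjusted over the list alone. Their median was 0.75 (camera adjusted p = 2.95e-05, adjusted p = 0.32 with an estimated correlation). The kainate receptor genes Grik1 and Grik3 were at 2.06 ± 0.12 and 1.86 ± 0.11. Metabotropic glutamate receptor genes were higher in 5 of 7 and lower in 1, the same adjusted over the list alone. Their median was 0.78 (camera adjusted p = 0.0138, adjusted p = 0.32 with an estimated correlation). Of 25 peptide and monoamine receptor genes 14 were higher and 4 lower, the same adjusted over the list alone. Their median was 0.52 (camera adjusted p = 0.000672, adjusted p = 0.324 with an estimated correlation). The adrenergic receptor gene Adra1a was at 1.82 ± 0.12 and the neurotensin receptor gene Ntsr2 at -2.73 ± 0.18.

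Set against the pan-neuronal genes of the same library, these families divided. The mean of the presynaptic, ionotropic glutamate receptor, potassium channel and sodium and calcium channel scores minus the pan-neuronal score differed by -0.06 between GFP+ and GFP- nuclei (exact permutation within age, two-sided, p = 0.144 over 98000 relabellings). The inhibitory neuron score minus the pan-neuronal score was higher in GFP+ nuclei by 0.54 and the opioid system score by 1.59, and the excitatory neuron score was lower, at -0.96, as was the score of excitatory peptides, at -1.75. Each of these 4 gave an exact permutation p of 2.04e-05, the smallest these relabellings can give, and 5.44e-05 after Benjamini-Hochberg adjustment over 16 relations. The opioid system score includes Pdyn, on whose promoter the sort rests, so part of its 1.59 was built into the sort. A score without Pdyn was not computed. Potassium channel genes alone were lower relative to pan-neuronal genes, at -0.17 (exact permutation p = 0.000694, adjusted 0.00139). GABA-A and glycine receptor and chloride transporter genes were lower relative to pan-neuronal genes, at -0.55 with the same exact permutation p of 2.04e-05. Their direct fold change had a median of 0.34, with 10 of 18 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0876). Relative scores also differed among GFP- libraries. Where the pan-neuronal score was 10.04 in ES14 and 9.16 in ES12, the inhibitory score was 7.35 and 5.84, and the excitatory score 7.37 and 7.11. A lower share of neurons in the GFP- sort could therefore move relative scores.

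All 14 oligodendrocyte genes (median -2.93, camera adjusted p = 8.46e-13), all 10 oligodendrocyte precursor genes (median -3.42, camera adjusted p = 2.33e-10), all 12 astrocyte genes (median -2.28, camera adjusted p = 1.61e-11) and 11 of 12 microglia genes (median -3.05, camera adjusted p = 1.87e-06) were lower, each also adjusted over the list alone. Each of these 4 lists had an adjusted p = 0.183 with an estimated correlation. Mbp, a myelin protein gene, was lower at -2.84 ± 0.19, the astrocyte glutamate transporter gene Slc1a2 at -2.04 ± 0.12 and the microglial receptor gene Cx3cr1 at -3.46 ± 0.26. Endothelial and mural genes were lower in 9 of 10 (median -2.63, camera adjusted p = 5.04e-05, adjusted p = 0.183 with an estimated correlation), also adjusted over the list alone. Meningeal fibroblast genes were lower in 6 of 8, also adjusted over the list alone (median -1.77, camera adjusted p = 0.00687, adjusted p = 0.32 with an estimated correlation). The perineuronal net and matrix list was lower in 8 of 12 genes and higher in 1, the same adjusted over the list alone. Their median was -1.31 (camera adjusted p = 0.000111, adjusted p = 0.183 with an estimated correlation). Hapln2 was at -3.32 ± 0.25 and Reln, a secreted protein of some dorsal horn neurons, at -1.13 ± 0.09. The matrix list shares Vcan with the oligodendrocyte precursor list. GFP- values come from neurons and other cells together. Whether neurons differ in the matrix genes, or in Ntsr2 of the receptor list, was not tested. Cell cycle genes were lower in 11 of 18 and higher in 1, or 12 and 1 adjusted over the list alone. Their median was -1.12 (camera adjusted p = 0.00457, adjusted p = 0.403 with an estimated correlation).

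The chromatin protein gene Hmga2, expressed mainly before birth in many tissues, was higher by 2.96 ± 0.10 (adjusted p = 3.93e-15). Its list of perinatal growth and imprinted genes had 7 of 15 higher and 3 lower, or 8 and 4 adjusted over the list alone. Their median was 0.27 (camera adjusted p = 0.0406, adjusted p = 0.216 with an estimated correlation). It was 0.52 without ES17, 0.51 without ES16 and 0.55 without ES2, and the list was not called without ES11 (adjusted p = 0.0557) or ES6 (adjusted p = 0.061). Of 15 immature neuron genes 7 were higher and 1 lower, also adjusted over the list alone. Their median was 0.57 (camera adjusted p = 0.0103, adjusted p = 0.183 with an estimated correlation). Gap43, a growth cone protein gene, was at 1.08 ± 0.14. Axon guidance genes were higher in 12 of 29 and lower in 7, the same adjusted over the list alone. Their median was 0.18 (camera adjusted p = 0.0643). Slit1 was at 2.02 ± 0.11 and Sema6a at -0.82 ± 0.09. Several other lists did not pass. Schwann cell genes were lower in 3 of 5 (median -1.92, camera adjusted p = 0.0889) and red blood cell genes higher in 1 of 5 (median 0.63, camera adjusted p = 0.409), both also adjusted over the list alone. Of 3 motor neuron genes 1 was higher and 1 lower, also adjusted over the list alone, with a median of -0.14 and a mean of 0.06 (camera adjusted p = 0.999). Immediate early genes were higher in 1 of 14 and lower in 3, or 1 and 1 adjusted over the list alone (median -0.23, camera adjusted p = 0.999). Cytosolic ribosomal protein genes were lower in 4 of 25, or 2 adjusted over the list alone (median -0.24, camera adjusted p = 0.273). No member of the 5 ependymal genes (median 0.47, camera adjusted p = 0.665) or the 7 mitochondrially encoded genes (median -0.61, camera adjusted p = 0.457) passed either way.

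By count, 8967 of 18614 genes differed between the populations, 4213 higher and 4754 lower in GFP+ nuclei, and 3337 of them by at least 2-fold (1052 higher and 2285 lower). In 2793 genes the libraries of the 2 populations did not overlap, in the same direction, at any age, a pattern that chance gives in 0.00204% of genes.

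**Figure D2:**
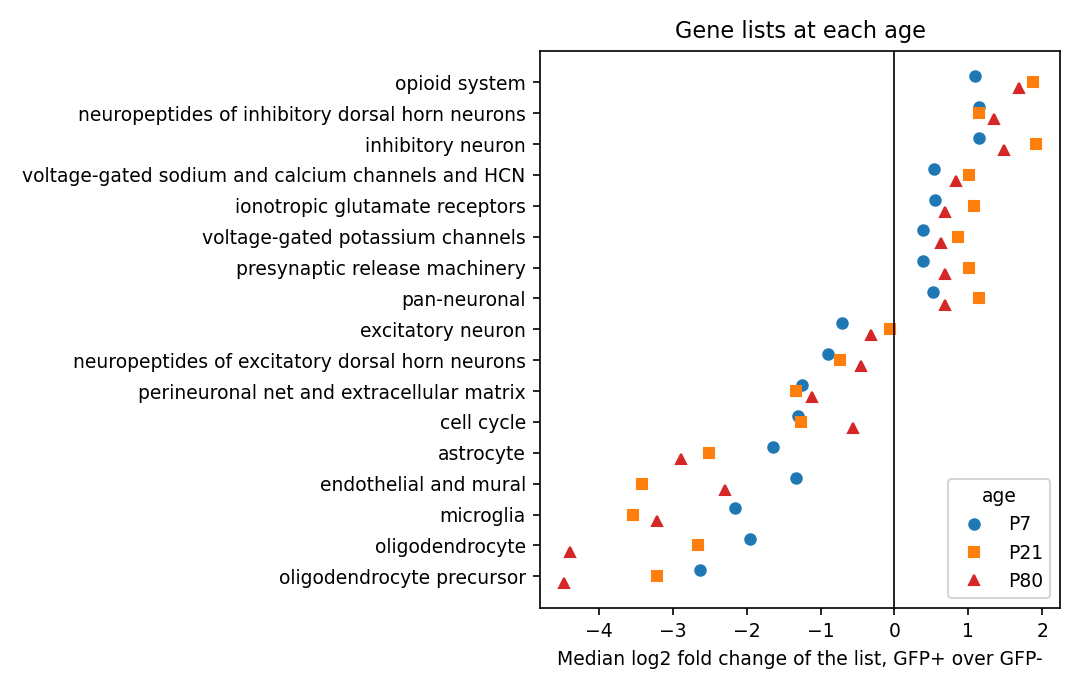
Median log2 fold change of GFP+ over GFP- nuclei for 17 gene lists at P7, P21 and P80. The medians of oligodendrocyte genes were -1.95, -2.66 and -4.39 at the 3 ages, and those of inhibitory neuron genes 1.15, 1.92 and 1.48.

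At P7, the question was the same within 1 age (n = 4 per population). Among genes of at least median expression, the highest fold changes were those of Robo3 at 4.16 ± 0.34 (adjusted p = 4.94e-08), Col6a6 at 3.84 ± 0.54, Sstr2 at 3.78 ± 0.22, Pnoc at 3.47 ± 0.42 and Abi3bp at 3.33 ± 0.29. The lowest were those of Pdgfra at -3.09 ± 0.31 (adjusted p = 1.05e-06), Atp13a5 at -2.97 ± 0.35, Cspg4 at -2.92 ± 0.45, the proliferation marker Mki67 at -2.83 ± 0.40 and Csf1r, a microglial growth factor receptor gene, at -2.79 ± 0.46. In the list of inhibitory neuropeptide and marker genes, Gal was higher by 5.22 ± 0.46, and Sst, which encodes somatostatin, was lower at -1.94 ± 0.23. Cell cycle genes were lower in 8 of 18, or 11 adjusted over the list alone. Their median was -1.31 (camera adjusted p = 6.56e-06, adjusted p = 0.299 with an estimated correlation). Top2a was at -2.73 ± 0.53 and Kif11 at -2.62 ± 0.43. Inhibitory neuron genes were higher in 6 of 12 and lower in 1, or 7 and 1 adjusted over the list alone (median 1.15, camera adjusted p = 0.000172, adjusted p = 0.31 with an estimated correlation). Oligodendrocyte genes were lower in 13 of 14, also adjusted over the list alone (median -1.95, camera adjusted p = 1.19e-11, adjusted p = 0.229 with an estimated correlation). In all, 3203 genes differed, 1315 higher and 1888 lower. The populations did not overlap in 5308 of all 18614 genes, or 28.5%, where chance gives 2.86%. Camera called 19 lists with the preset correlation and 0 with an estimated one (6 at an unadjusted p under 0.05, adjusted p of the 19 between 0.119 and 0.504). The immediate early list had a median of -0.18 and a test direction of up, and the motor neuron list a median of -0.26 and a mean of 0.01, neither called. A fit of the P7 libraries alone called 5093 genes.

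At P21 (n = 3 per population) Robo3 at 4.51 ± 0.39 (adjusted p = 1.21e-07), Sstr2 at 4.43 ± 0.26, Pnoc at 4.14 ± 0.48, Col6a6 at 4.12 ± 0.62 and Nos1 at 3.94 ± 0.32 had the highest fold changes among genes of at least median expression. The lowest were those of Pdgfra at -3.75 ± 0.36 (adjusted p = 4.3e-07), Cspg4 at -3.73 ± 0.52, Csf1r at -3.70 ± 0.53, Pmp22, a myelin protein gene, at -3.56 ± 0.74 and Ptprb, an endothelial phosphatase gene, at -3.49 ± 0.66. The endothelial and mural median was -3.42 and the microglia median -3.54. They were -1.96 and -2.68 without the GFP- library ES16, and -4.06 and -4.37 without ES14. Both lists stayed called with the preset correlation. The serotonin receptor gene Htr1a was higher by 2.88 ± 0.33, and peptide and monoamine receptor genes were higher in 13 of 25 and lower in 1, or 14 and 1 adjusted over the list alone. Their median was 0.98 (camera adjusted p = 1.71e-05, adjusted p = 0.214 with an estimated correlation). Inhibitory neuron genes were higher in 10 of 12, also adjusted over the list alone. Their median was 1.92 (camera adjusted p = 1.12e-06, adjusted p = 0.181 with an estimated correlation). GABA-A and glycine receptor and chloride transporter genes were higher in 8 of 18 and lower in 1, or 10 and 1 adjusted over the list alone. Their median was 0.56 (camera adjusted p = 0.00928, adjusted p = 0.452 with an estimated correlation). Without the GFP- library ES14 it was 0.88, and without ES16 it was 0.40 and the list was not called (camera adjusted p = 0.106). Cytosolic ribosomal protein genes were lower in 4 of 25, and in 0 adjusted over the list alone (median -0.60, camera adjusted p = 0.0426, adjusted p = 0.537 with an estimated correlation). Without the P21 GFP- library ES16 the median of these genes was 0.01 and the test direction down (camera adjusted p = 0.835), and without ES12 or ES14 of that group it was -0.92 or -1.07. The list was not called either without the GFP+ libraries ES11 or ES13 (camera adjusted p = 0.0546 and 0.0569). In ES16 the mitochondrial transcript mt-Co1 had a value of 12843, against 169 to 1188 in the other 21 libraries, and the immediate early gene Fos 385, against 11.0 to 87.0. Of 18614 genes, 6128 differed, 2727 higher and 3401 lower. In 7400 of all genes, or 39.8%, the populations did not overlap, where chance gives 10%. Camera called 22 lists with the preset correlation and 0 with an estimated one (6 at an unadjusted p under 0.05, adjusted p of the 22 between 0.181 and 0.537). The excitatory neuron list had a median of -0.05 and a mean of 0.03, and the motor neuron list -0.78 and 0.09, neither called. A fit of the P21 libraries alone called 2743 genes. The SD of the pan-neuronal score at P21 was 0.46 in GFP- and 0.09 in GFP+ libraries, so a spread shared by all groups may be too small here.

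At P80 (n = 4 per population), among genes of at least median expression, Robo3 was higher by 4.51 ± 0.34 (adjusted p = 3.68e-09), Pkd1l2 by 4.40 ± 1.29 (adjusted p = 0.0155), Pnoc by 4.17 ± 0.42, Sstr2 by 3.96 ± 0.22 and Rasgrp1 by 3.90 ± 0.30. The lowest fold changes, Gjc3 at -5.53 ± 0.37 (adjusted p = 1.82e-09), Aspa at -5.47 ± 0.37, Plxnb3 at -5.47 ± 0.38, Tmem63a at -5.21 ± 0.33 and Sec14l5 at -5.19 ± 0.40, included Aspa of the oligodendrocyte list. Oligodendrocyte genes were lower in all 14, also adjusted over the list alone. Their median was -4.39 (camera adjusted p = 1.12e-20, adjusted p = 0.0925 with an estimated correlation). Opioid system genes, among them Pdyn, whose rise was built into the sort, were higher in 6 of 7, or all 7 adjusted over the list alone. Their median was 1.69 (camera adjusted p = 4.99e-06, adjusted p = 0.195 with an estimated correlation). Axon guidance genes were higher in 9 of 29 and lower in 3, or 9 and 4 adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.0196, adjusted p = 0.332 with an estimated correlation), or 0.11 without the GFP- library ES8. Sema5a was at 1.18 ± 0.15. The pacemaker channel gene Hcn2 was lower at -1.99 ± 0.31 and the chloride importer gene Slc12a2 at -2.62 ± 0.26. GFP- nuclei include those of glia, so whether neurons differ in Hcn2 and Slc12a2 was not tested. In all, 5214 genes differed, 2348 higher and 2866 lower. Of all 18614 genes 5965, or 32.0%, did not overlap, where chance gives 2.86%. Camera called 19 lists with the preset correlation and 0 with an estimated one (7 at an unadjusted p under 0.05, adjusted p of the 19 between 0.0925 and 0.363). The ependymal list had a median of -0.21 and a mean of 0.24, and the cytosolic ribosomal protein list 0.01 and -0.01, neither called.

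The next comparisons asked which genes change with age within pDyn-lineage nuclei. Animals differed between ages, and library codes ran in blocks by age: ES1 to ES8 at P80, ES11 to ES16 at P21 and ES17 to ES24 at P7. A difference in handling between these blocks, if there was one, could not be told apart from age. From P7 to P21 (n = 4 and 3) the highest fold changes among genes of at least median expression were those of Spag5, a mitotic spindle protein gene, at 2.47 ± 0.20 (adjusted p = 3.57e-07) and the sodium channel subunit gene Scn4b at 2.23 ± 0.42 (adjusted p = 0.00539). They were followed by Dock5 at 1.70 ± 0.32, the potassium channel gene Kcna1 at 1.69 ± 0.26 and Faim2 at 1.35 ± 0.17. The lowest were those of the matrix protein gene Tnc at -2.62 ± 0.57 (adjusted p = 0.0175), Col11a2 at -2.26 ± 0.30, Mki67 at -2.13 ± 0.43, Slc38a3 at -1.83 ± 0.34 and Gfap, an astrocyte filament gene, at -1.71 ± 0.25. Immature neuron genes fell: 4 of 15 were lower at P21, or 12 adjusted over the list alone, with a median of -0.85 (camera adjusted p = 3.87e-11, adjusted p = 0.000316 with an estimated correlation). Among them were Tubb2b at -1.71 ± 0.24, Nnat at -1.38 ± 0.27, Sox11 at -1.15 ± 0.24 and Marcksl1 at -1.47 ± 0.32. In GFP- libraries the score of this list was also lower at P21, at 5.75 to 6.19 against 6.67 to 6.83 at P7. The neuropeptide Y receptor gene Npy1r rose by 1.15 ± 0.20 and the imprinted gene Dlk1 by 2.18 ± 0.40.

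Potassium channel genes rose in 2 of 24 and fell in 1 between P7 and P21, or 4 and 1 adjusted over the list alone. Their median was 0.13 (camera adjusted p = 0.0381, adjusted p = 0.91 with an estimated correlation), and the list was not called without ES19, ES23 or ES13 (adjusted p between 0.0595 and 0.0757). Oligodendrocyte precursor genes fell in 3 of 10, or 7 adjusted over the list alone (median -1.21, camera adjusted p = 5.81e-09, adjusted p = 0.333 with an estimated correlation). Astrocyte genes fell in 4 of 12, or 6 adjusted over the list alone (median -0.77, camera adjusted p = 8.88e-06, adjusted p = 0.681 with an estimated correlation). The matrix list fell in 5 of 12 (median -0.23, camera adjusted p = 0.00716, adjusted p = 0.604 with an estimated correlation) and the cell cycle list in 1 of 18 (median -0.76, camera adjusted p = 0.00899, adjusted p = 0.91 with an estimated correlation). The endothelial and mural list fell in 1 of 10 (median -0.49, camera adjusted p = 0.0166, adjusted p = 0.784 with an estimated correlation) and the axon guidance list in none of 29 (median -0.16, camera adjusted p = 0.0381, adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, these 4 lists had 5, 1, 2 and 0 lower, and the matrix list 1 higher. Without the P21 library ES13 the cell cycle median was -0.44 and the list was not called (camera adjusted p = 0.0924). The axon guidance list was not called without ES17, ES19, ES21 or ES15 (adjusted p between 0.0595 and 0.142). Of 18614 genes 433 changed, 161 up and 272 down. In 3824 of all genes, or 20.5%, the ages did not overlap, where chance gives 5.71%. The pan-neuronal, excitatory peptide and perinatal growth lists had medians of -0.03, 0.09 and -0.07 that differed in sign from their test direction or mean, and none was called. The count was 2068 in a fit of the GFP+ libraries alone, 694 with DESeq2 on recovered reads, 368 with edgeR and 802 without the P21 GFP- library ES16, where 18461 genes were tested and the shared spread differed. Leaving out 1 GFP+ library gave 188 (P21 library ES11), 199 (P21 library ES13), 217 (P7 library ES23), 232 (P21 library ES15), 232 (P7 library ES19), 260 (P7 library ES21) or 355 (P7 library ES17).

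From P21 to P80 (n = 3 and 4) the genes that changed in GFP+ nuclei were lower at P80. Among genes of at least median expression the lowest fold change was that of Gpr17, a receptor gene of oligodendrocyte precursors, at -2.84 ± 0.37 (adjusted p = 0.00411). It was followed by the myelin genes Mobp at -2.61 ± 0.39 and Cldn11 at -2.49 ± 0.42, Gjc3 at -2.57 ± 0.40 and Plxnb3 at -2.38 ± 0.41. Oligodendrocyte genes fell in 9 of 14, or 13 adjusted over the list alone. Their median was -2.05 (camera adjusted p = 4.87e-40, adjusted p = 0.0211 with an estimated correlation). Oligodendrocyte precursor genes fell in 4 of 10, or 8 adjusted over the list alone (median -1.65, camera adjusted p = 2.69e-20, adjusted p = 0.0211 with an estimated correlation). Astrocyte genes fell in 3 of 12, or 10 adjusted over the list alone (median -0.98, camera adjusted p = 2.69e-20, adjusted p = 0.0304 with an estimated correlation). The value of Mbp in GFP+ nuclei was 3955 ± 491 at P7 (SD, n = 4), 3280 ± 250 at P21 (n = 3) and 729 ± 76.3 at P80 (n = 4). In GFP- nuclei it was 14042 ± 1853, 22026 ± 12788 and 14302 ± 8652 at the same ages. In the inhibitory neuron, opioid system, presynaptic and channel lists no member passed over all genes or adjusted over the list alone. Microglia genes had a median of -1.01 with no member passing either way (camera adjusted p = 0.000856, adjusted p = 0.76 with an estimated correlation), and the list was not called without ES13 (adjusted p = 0.0943). Meningeal genes had a median of -1.39 with 0 of 8 passing over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00739, adjusted p = 0.76 with an estimated correlation). Cell cycle genes had a median of -0.56, with Top2a passing both over all genes and adjusted over the list alone at -2.73 ± 0.57 (camera adjusted p = 0.00797, adjusted p = 0.95 with an estimated correlation). Without the P21 library ES11 that median was -0.39 and the list was not called (camera adjusted p = 0.164). Red blood cell genes had a median of -5.08 with 0 of 5 passing over all genes and 4 lower adjusted over the list alone (camera adjusted p = 5.19e-06, adjusted p = 0.086 with an estimated correlation). Immediate early genes had a median of 0.38 with no member passing either way (camera adjusted p = 0.0419, adjusted p = 0.95 with an estimated correlation). The list was not called without ES11, ES13, ES5 or ES7 (camera adjusted p between 0.114 and 0.247), and its median without ES5 was 0.25.

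In count, 45 genes fell from P21 to P80 and 0 rose in limma, with 1006 genes at an unadjusted p under 0.05 in either direction. DESeq2 gave 66 lower and 4 higher and edgeR 5 lower and 0 higher. Over all 18614 genes the ages did not overlap in 2382, or 12.8%, where chance gives 5.71%. At P7, 42 of the 45 were lower in GFP+ than in GFP- nuclei and 0 higher, in the same fit and with the same estimate of the spread. The peptide and monoamine receptor, ionotropic glutamate receptor and mitochondrial lists had medians of 0.08, 0.01 and 0.16 that differed in sign from their mean, and none was called. The count was 201 (170 lower) in a fit of the GFP+ libraries alone and 21 with a pseudocount of 5. It was 3 without the P21 library ES11, 16 without ES13, 29 without the P80 libraries ES1 or ES3, and 20 without ES5.

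**Figure D3:**
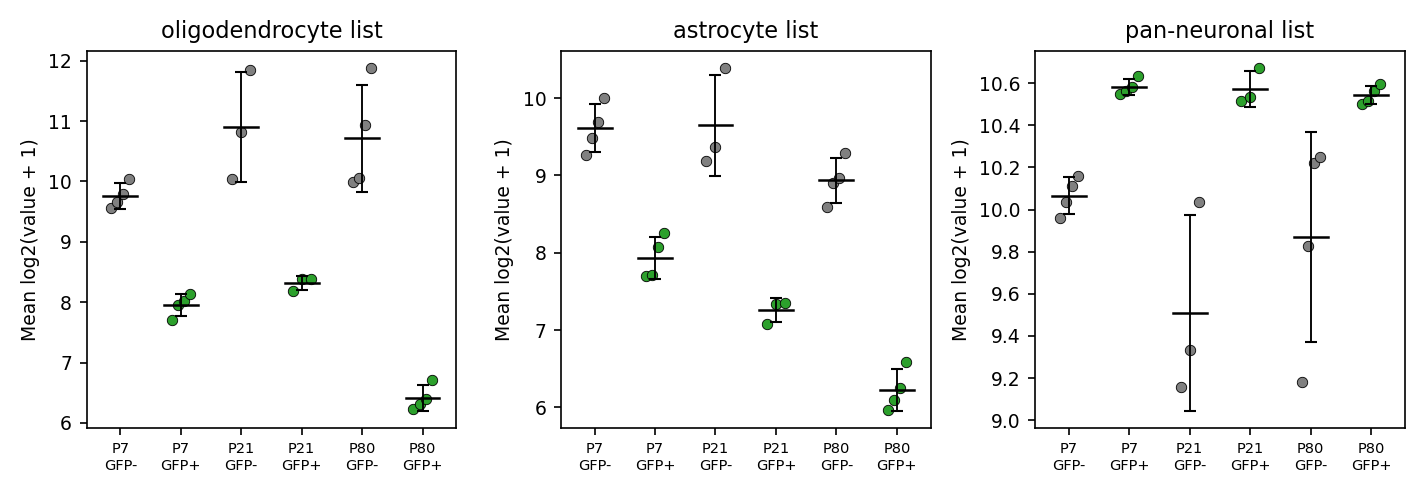
Mean log2(value + 1) of the oligodendrocyte, astrocyte and pan-neuronal lists in each library, with the group mean and SD. In GFP+ libraries the oligodendrocyte means were 7.95, 8.32 and 6.41 at P7, P21 and P80, and the pan-neuronal means 10.58, 10.57 and 10.54.

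From P7 to P80 (n = 4 per age) the highest fold changes in GFP+ nuclei among genes of at least median expression were those of Scn4b at 2.37 ± 0.39 (adjusted p = 0.000371), Spag5 at 2.35 ± 0.19 (adjusted p = 6.23e-08), the chloride channel family gene Ano3 at 1.72 ± 0.23, the small RNA gene Scarna13 at 1.70 ± 0.40, and the perineuronal net gene Hapln4 at 1.64 ± 0.42. They were followed by Abca6 at 1.62 ± 0.26, the glutaminase gene Gls2 at 1.61 ± 0.27, the immediate early gene Egr1 at 1.59 ± 0.45 and the prohormone convertase gene Pcsk1 at 1.55 ± 0.18. The lowest were those of Gpr17 at -4.39 ± 0.35 (adjusted p = 6.9e-08), Tcf7l2 at -3.42 ± 0.33, Cspg4 at -3.35 ± 0.45, Mki67 at -3.35 ± 0.40, and Col11a2 at -3.29 ± 0.28. Next were Bcas1 at -3.23 ± 0.32, Nid1 at -3.18 ± 0.35, Enpp6 at -3.13 ± 0.33, Olig2 at -3.02 ± 0.38 and Pdgfra at -2.87 ± 0.31. Gpr17, Cspg4, Bcas1, Enpp6, Olig2 and Pdgfra belong to the oligodendrocyte and precursor lists. The mean value of Gpr17 also fell in GFP- nuclei, from 2039 at P7 to 290 at P80, beside 320 and 15.3 in GFP+ nuclei.

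**Figure D4:**
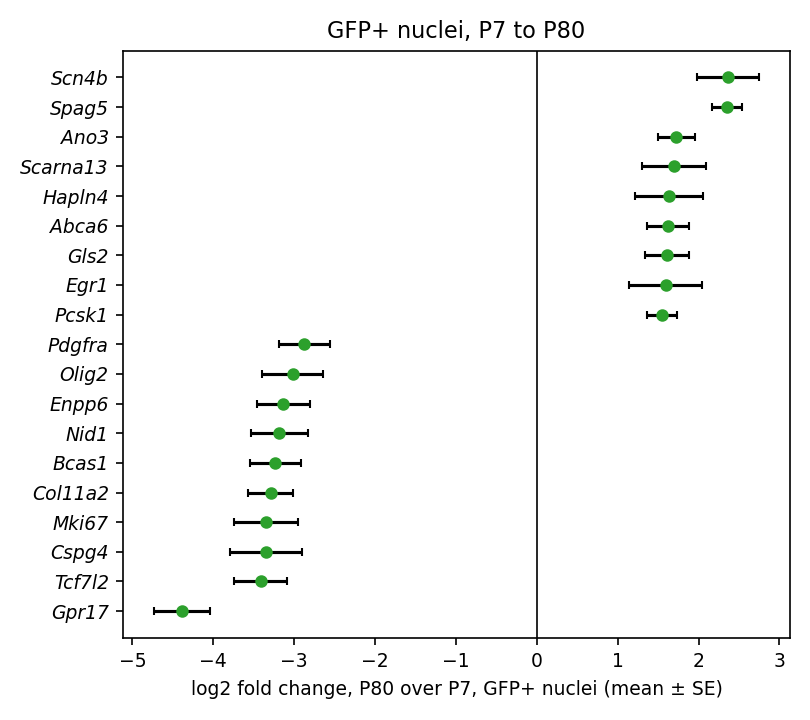
Log2 fold change from P7 to P80 in GFP+ nuclei with its standard error (n = 4 per age) for 9 of the 10 highest and the 10 lowest genes of at least median expression. Spag5 lies at 2.35 and Gpr17 at -4.39.

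Within neuronal families most genes did not pass between P7 and P80, and a few did. Potassium channel genes rose in 3 of 24 and fell in 1, or 6 and 1 adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.00798, adjusted p = 0.779 with an estimated correlation). Kcna1 rose by 1.42 ± 0.24, Kcna2 by 1.01 ± 0.21 and Kcnd3 by 0.49 ± 0.15, and Kcnn3 fell, at -0.97 ± 0.23. Of 24 sodium, calcium and HCN channel genes 3 rose, also adjusted over the list alone, among them Scn4b and the subunit gene Scn2b (0.75 ± 0.24). The median of these 24 was 0.08 (camera adjusted p = 0.103). The vesicle fusion gene Snap25 rose by 1.09 ± 0.21 and Stx1a fell, at -0.86 ± 0.16. Glycine receptor genes Glra4 and Glrb rose by 1.04 ± 0.28 and 0.53 ± 0.16, and the kainate receptor genes Grik1 and Grik5 fell, at -0.72 ± 0.19 and -0.49 ± 0.13. Among peptides Tac2 rose by 1.81 ± 0.28 and Penk by 0.81 ± 0.22, and Nts and Calb2 fell, at -1.28 ± 0.35 and -1.38 ± 0.27. Immediate early genes rose in 3 of 14, also adjusted over the list alone (median 0.91, camera adjusted p = 0.00334, adjusted p = 0.539 with an estimated correlation). They were Egr3 at 1.85 ± 0.48, Egr1, and Arc at 0.99 ± 0.29. In the pan-neuronal list Snap25 rose and Stmn2 fell, at -0.88 ± 0.19, also adjusted over the list alone, with a median of 0.00 and a mean of -0.04 (camera adjusted p = 0.802).

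Immature neuron genes fell in 10 of 15 between P7 and P80, or 12 adjusted over the list alone. Their median was -1.03 (camera adjusted p = 2.62e-10, adjusted p = 0.000691 with an estimated correlation). Marcksl1 was at -2.40 ± 0.29, Nnat at -1.52 ± 0.25 and Sox4 at -1.32 ± 0.26. The immature neuron score was lower with age in GFP- libraries too, at 6.67 to 6.83 at P7 and 5.56 to 5.77 at P80. A change of the GFP+ to GFP- difference between these ages was not called for this list (median 0.13, camera adjusted p = 0.411). The matrix list fell in 5 of 12 and rose in 1, or 6 and 1 adjusted over the list alone. Their median was -0.66 (camera adjusted p = 0.00123, adjusted p = 0.295 with an estimated correlation). Reln was at -1.17 ± 0.14 and Ncan at -1.20 ± 0.19. Cell cycle genes fell in 5 of 18, or 7 adjusted over the list alone (median -1.31, camera adjusted p = 0.000104, adjusted p = 0.539 with an estimated correlation). Cytosolic ribosomal protein genes fell in 1 of 25, or 5 adjusted over the list alone (median -0.44, camera adjusted p = 0.00209, adjusted p = 0.651 with an estimated correlation). All 10 oligodendrocyte precursor genes fell, also adjusted over the list alone. Their median was -2.94 (camera adjusted p = 1.69e-18, adjusted p = 0.0285 with an estimated correlation). Astrocyte genes fell in 9 of 12, or 11 adjusted over the list alone (median -1.84, camera adjusted p = 1.5e-15, adjusted p = 0.0756 with an estimated correlation). Oligodendrocyte genes fell in 10 of 14, or 11 adjusted over the list alone (median -1.74, camera adjusted p = 7.88e-11, adjusted p = 0.321 with an estimated correlation). Endothelial and mural genes fell in 4 of 10, also adjusted over the list alone (median -1.23, camera adjusted p = 0.00568, adjusted p = 0.536 with an estimated correlation). Meningeal genes fell in 3 of 8, or 5 adjusted over the list alone (median -1.52, camera adjusted p = 0.00654, adjusted p = 0.539 with an estimated correlation).

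Altogether 1747 genes changed from P7 to P80 in GFP+ nuclei, 647 up and 1100 down. Over all 18614 genes 4644, or 24.9%, did not overlap between the ages, where chance gives 2.86%. Of the 1100 that fell, 687 (62.5%) were lower and 166 higher in GFP+ than in GFP- nuclei averaged over ages, where independent lists would share 281 and 249. Of the 647 that rose, 250 (38.6%) were higher and 123 lower, where 146 and 165 would be shared. With equal numbers at P7 and P80 these contrasts are uncorrelated when the genes do not change, but they share the estimate of the spread, so part of the excess may come from it. The excitatory peptide and Schwann cell lists had medians of -0.10 and 0.17 that differed in sign from their test direction or mean, and neither was called. The count was 4203 in a fit of the GFP+ libraries alone and 1085 without the P80 library ES5.

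The last comparison asked whether the difference between the populations changes with age. The smallest p was that of Spag5, whose GFP+ to GFP- difference was higher at P80 than at P7 by 2.68 ± 0.27 (adjusted p = 2.89e-05). The same change was higher for Zbtb1 (1.17 ± 0.15), Adamtsl2 (1.48 ± 0.22) and Ptpre (0.87 ± 0.13). It was lower for the nuclear noncoding RNA gene Neat1 (-2.81 ± 0.36), Adamtsl1 (-2.33 ± 0.31), Prr5l (-3.25 ± 0.44), Cntn2 (-2.67 ± 0.38) and Pde8a (-2.74 ± 0.41). The highest adjusted p of these 9 genes was 0.00739. Spag5 had a value of 55.8 ± 11.6 in GFP+ nuclei at P7 (SD, n = 4), 313 ± 56.2 at P21 (n = 3) and 286 ± 36.8 at P80 (n = 4). In GFP- nuclei it was 290 ± 76.6, 294 ± 39.3 and 229 ± 47.8. In the oligodendrocyte list 12 of 14 genes passed with a lower GFP+ to GFP- difference at P80, and 14 adjusted over the list alone. Their median was -2.53 (camera adjusted p = 2.07e-26, adjusted p = 0.122 with an estimated correlation). Aspa was at -3.17 ± 0.52 and Mag at -3.02 ± 0.53. Hcn2 at -2.30 ± 0.44, Sema5a at 1.14 ± 0.21 and Hapln2 at -2.95 ± 0.58 also passed, and whether their changes arise in neurons was not tested. In the inhibitory neuron, opioid system and pan-neuronal lists no member passed over all genes or adjusted over the list alone (camera adjusted p = 0.0539, 0.13 and 0.208), with 2203 genes of all at an unadjusted p under 0.05.

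The interaction test of limma with 2 degrees of freedom called 177 genes, of which 41 had a higher and 136 a lower difference at P80 than at P7. It called 162 with edgeR and 628 with DESeq2. Lists with opposite signs of median and mean or test were the Schwann cell, metabotropic glutamate receptor, immature neuron and perinatal growth lists, with medians of -0.37, 0.09, 0.13 and 0.09 and none called. The count was 394 without the P21 GFP- library ES16, 440 without ES14 and 350 without ES12 of the same group, and 287 without the P80 GFP- library ES2. It was 68 without ES4 of that group, and 68, 106 and 81 without the P7 GFP- libraries ES18, ES22 and ES24. Leaving out GFP+ libraries gave 94, 110 and 92 without the P7 libraries ES17, ES19 and ES21, and 98, 79 and 113 without the P80 libraries ES1, ES3 and ES5.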

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

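The tests of a fall in the whole tissue, of an equal loss of carried-over RNA with astrocyte genes for comparison, of RNA from an animal of the other sex and of RNA from outside the nucleus, and the omission of single libraries in the comparisons of populations, were chosen after the results they measure had been seen; the remaining tests of this part were chosen before.

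Glial transcripts fell in GFP+ nuclei towards P80, with oligodendrocyte scores of 7.95, 8.32 and 6.41 at P7, P21 and P80 beside pan-neuronal scores of 10.58, 10.57 and 10.54, and a fall in the tissue as a whole is argued against for oligodendrocyte transcripts, whose GFP- score was 0.953 higher at P80 than at P7 (SE 0.456, exact permutation p = 0.0571, two-sided; 0.564 without the P80 library ES8), against a change of -1.54 in GFP+ nuclei, and moved by -0.185 from P21 to P80 (0.288 without ES12, -0.617 without ES16), against -1.90. A change with age in the nuclei that express the GFP was not tested and stays open, and for oligodendrocyte precursor and astrocyte transcripts a fall in the tissue may contribute, since the GFP- score moved by -1.33 for the precursors (SE 0.336, p = 0.0286 in the same permutation, the smallest it can give) and by -0.672 for astrocytes (SE 0.211, p = 0.0571), against -2.91 and -1.71 in GFP+ nuclei, and from P21 to P80 by -0.759 and -0.709 (-0.275 and -0.337 without ES12), against -1.60 and -1.03. Fewer glial nuclei, or less of their RNA, in the P80 GFP+ sorts may account for the fall. Of 380 unlisted genes at least 4-fold lower in GFP+ nuclei at P7, 81.3% had a lower GFP+ mean at P80 than at P21, against 52.8% of all genes. This is close to the bound of 80% set for this test. The share cannot set this explanation apart from a fall in the tissue or less carried-over RNA, which would lower the same genes. The change of these 380 genes in GFP- nuclei was not examined. An equal loss of RNA carried over from all other cell types cannot be told apart from fewer glial nuclei. The oligodendrocyte minus microglia score moved by -0.836 (exact permutation p = 0.00606, two-sided), past the bound set in advance. However, 9 of 12 microglia genes averaged under 10 in P80 GFP+ nuclei and so lay near the floor. With astrocyte genes for comparison the oligodendrocyte minus astrocyte score of GFP+ nuclei moved by -0.872 from P21 to P80 (SE 0.0564, exact permutation p = 0.0571, the smallest it can give) and by 0.17 from P7, but the GFP+ to GFP- log2 ratios of the 12 astrocyte genes at P80 ran from -4.24 to -1.05, and expression of some in GFP+ nuclei themselves could hide an equal loss.

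The P21 GFP- library ES16 stood apart, with Spearman correlations of 0.759 to 0.886 to the other 21 libraries, where pairs of the others had 0.831 to 0.986. Greater depth is argued against as the cause: thinned from 10849169 to 5358313 reads, its median correlation with the other 10 GFP- libraries was 0.844, against 0.845 before thinning and a lowest value of 0.916 among the others. More RNA from outside the nucleus may contribute, since its score of mitochondrially encoded transcripts was 3.33 above the highest other GFP- library and its Malat1 share of 4.85% was below the lowest of the others, 5.65%. RNA of an animal of the other sex may also be present, since Xist was 14.7-fold above the highest library low for it and the Y-linked sum 66.4-fold. Xist reached 9.96% and the Y-linked sum 63.8% of the mean of the libraries high for each. No biological explanation was tested, and both open explanations rest on this 1 library.

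Synaptic and channel genes and inhibitory neuron genes were both higher in GFP+ nuclei. A lower share of neurons among the GFP- nuclei may account for the synaptic and channel lists, since their mean score relative to the pan-neuronal score differed by -0.0552 (exact permutation p = 0.144) between the populations. For inhibitory neuron genes the score relative to the pan-neuronal one was higher by 0.539 in GFP+ nuclei (exact permutation p = 2.04e-05, the smallest the 98000 relabellings can give). This passed the bound set in advance but cannot settle the same explanation, since the relative score also differed among GFP- libraries. The inhibitory and pan-neuronal scores were 5.84 and 9.16 in ES12, 5.84 and 9.18 in ES8, and 6.44 and 9.34 in ES16. They were 7.35 and 10.04 in ES14 and 7.46 and 10.25 in ES2. An inhibitory identity of pDyn-lineage neurons is a candidate explanation for the inhibitory neuron genes, as a hypothesis on the same data. A lower share of neurons in the GFP- sort stays open for the inhibitory neuron genes. That share alone would not make neuronal genes lower in GFP+ nuclei. The score of excitatory peptides differed by -0.99 (exact permutation p = 2.04e-05), which argues against it as the only difference between the sorts. The excitatory neuron score differed by -0.21 (exact permutation p = 0.0549). A difference in the mix of neurons, which could include an inhibitory identity, also stays open.

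The count of genes with an interaction of age and population was 177, between 68 (without the P7 GFP- library ES18, and likewise without the P80 GFP- library ES4) and 440 (without the P21 GFP- library ES14) when 1 library was left out. For 9 genes the GFP+ to GFP- difference changed between P7 and P80 with p among the 10 smallest: Spag5 by 2.68, Zbtb1 by 1.17, Neat1 by -2.81, Adamtsl1 by -2.33, Prr5l by -3.25, Adamtsl2 by 1.48, Cntn2 by -2.67, Ptpre by 0.87 and Pde8a by -2.74. For 9 lists camera with the preset correlation called a change of that difference: the median was -2.53 for oligodendrocyte, -1.78 for oligodendrocyte precursor, -1.24 for astrocyte, -0.85 for microglia, -1.09 for meningeal fibroblast, 0.50 for peptide and monoamine receptor, 0.28 for sodium, calcium and HCN channel, 0.23 for axon guidance and 0.85 for cell cycle genes. With an estimated correlation limma's camera called 0 of them (3 of 31 lists at an unadjusted p under 0.05), with adjusted p between 0.122 and 0.752. Without the P80 GFP- library ES8 the median was -0.01 for sodium, calcium and HCN channel, 0.07 for peptide and monoamine receptor, 0.06 for axon guidance and -0.42 for microglia genes, and none of these 4 lists was called (adjusted p between 0.14 and 0.966). The meningeal median was -0.48 without the P7 GFP- library ES20 (adjusted p = 0.165), the axon guidance median 0.37 without ES2 and the peptide and monoamine receptor median 0.32 without ES24 (adjusted p = 0.0643). Of 16 single omissions, 10 left the sodium, calcium and HCN channel list uncalled, 7 each the microglia and the peptide and monoamine receptor lists, 6 the meningeal list and 1 the axon guidance list, whereas the oligodendrocyte, precursor, astrocyte and cell cycle lists were called in all 16. The 9 lists were 5 without ES8 or without the GFP+ libraries ES17, ES1 or ES5, 15 without the P80 GFP- library ES2 and 16 without ES6.

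In 13 of 224 sets of 4 libraries, or 5.80%, 1 library lay far from the other 3, and chance gives about 5%, or 1 in 20. In the P7 GFP- group these were the lowest axon guidance score, 8.65, the highest Aspa value, 611 (both ES20), and the highest red blood cell score, 5.22 (ES22). In the P7 GFP+ group they were the lowest inhibitory peptide score, 6.60, and the highest Aspa value, 123 (both ES21), the lowest mitochondrial score, 6.75 (ES19), and the highest Robo3 value, 691 (ES23). In the P80 GFP- group ES8 had the lowest opioid system score, 4.72, the lowest GABA-A and glycine receptor score, 7.57, and the highest red blood cell score, 6.72. In the P80 GFP+ group ES5 had the lowest immature neuron score, 5.94, and the highest Cdh19 value, 18.6, and ES7 the highest Aspa value, 94.9.

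Other splits of the same libraries into groups of the same sizes were fitted for each count of genes, and in each comparison only 1 split, the real one, called as many. That is a share under 0.05, not adjusted over the comparisons, averaged over ages (8967 genes, highest other of 100 splits 6168), at P7 (3203, highest other of 35 splits 19) and at P80 (5214, highest other 1). It is so too from P7 to P21 (433, highest other 1), P21 to P80 (45, highest other 5), P7 to P80 (1747, highest other 0) and for the interaction (177, highest other of 100 splits 124). Splits that mix differing libraries widen the spread, so their low counts do not exclude chance. With 1 library left out the count fell as low as 3 from P21 to P80 and 68 for the interaction, below the highest other split. At P21 the 10 splits are too few for a share under 0.05, with 6128 genes in the real split and 1 in the highest other.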

How the results depend on the processing

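The edgeR test, the fits without the P21 GFP- library ES16, the omission of single libraries in the comparisons of populations and the list tests under other settings were chosen after seeing the data. No paired analysis was possible because the columns carry no animal or replicate number, so fits with a replicate block or with each animal left out, and camera with animal as a block, were not run. Fits with sex as a covariate were not run either, since the labels' sexes could not be joined to single columns and sex was not assigned from the values. Pdyn was called under every setting run, with a fold change of 5.47 to 6.44, and of 5.93 to 6.38 when 1 library was left out. The 171 gene values printed with a test were compared under alternatives 3719 times. In 121 of these the gene no longer passed, 99 of them when 1 library was left out and 12 from the 2-fold floor. None changed sign. All 171 had passed as reported, and most were chosen by fold change or p in the same data. Few losses and no change of sign were therefore likely from the start. In each count, genes called both as reported and under an alternative always had the same sign.

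By its construction, a 2-fold floor lowered the counts to 3337 averaged over ages, 1730 at P7, 3803 at P21, 2898 at P80, 228 from P7 to P21 and 832 from P7 to P80. Fits of fewer libraries, which take both the spread and the genes to test from those libraries alone, gave 5093 at P7 and 2743 at P21 (libraries of that age), and 2068 from P7 to P21, 201 from P21 to P80 and 4203 from P7 to P80 (GFP+ libraries). Without ES16 the counts were 802 from P7 to P21 and 394 for the interaction. DESeq2 gave 694 from P7 to P21, 70 from P21 to P80 and 628 for the interaction, with no adjusted p for 245 genes (260 for the interaction), and edgeR 5 from P21 to P80. With a pseudocount of 5 the count from P21 to P80 was 21, and 5 lists were called for the change of the population difference. Apart from the 2-fold floor, the cause of these moves was not tested. The groups differed in spread, which an estimate shared by all groups does not allow for. The SD of the pan-neuronal score was 0.46 in P21 and 0.50 in P80 GFP- libraries, against 0.04 to 0.09 in the other groups. Errors from the shared estimate may thus be too small where these GFP- groups enter and too large elsewhere. With an estimated correlation camera called 0 lists averaged over ages, at P7, at P21, at P80 and for the change of the population difference, 1 from P7 to P21, 3 from P21 to P80 and 2 from P7 to P80, since the estimated correlations exceeded the preset one.

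Leaving out 1 library at a time gave 8459 to 9405 genes averaged over ages, 2244 to 2717 at P7, 4828 to 7335 at P21, 3888 to 5552 at P80, 188 to 355 from P7 to P21, 3 to 48 from P21 to P80, 1085 to 1411 from P7 to P80 and 68 to 440 for the interaction. Lists called were 19 to 22 averaged over ages, 18 to 22 at P7, 19 to 23 at P21, 18 to 20 at P80, 7 to 10 from P7 to P21, 6 to 9 from P21 to P80, 11 to 12 from P7 to P80 and 5 to 16 for the change of the population difference.

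In simulated data 2-fold changes were recovered in 25.4% of cases from P21 to P80 (18219 genes) and 11.9% for the interaction (18227 genes). These data held no shifts that many genes share within a library.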

Other observations

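Several gene groups beyond those compared above moved relative to pan-neuronal genes. The neuropeptide and marker genes of inhibitory dorsal horn neurons were higher in GFP+ nuclei by 0.69 relative to the pan-neuronal score (exact permutation within age, two-sided, p = 2.04e-05, the smallest the relabellings can give), with 0.89 at P7, 0.44 at P21 and 0.76 at P80. Axon guidance genes were lower relative to pan-neuronal genes, at -0.46 (exact permutation p = 8.16e-05), and immediate early genes at -0.83 (exact permutation p = 0.00657). Without that relation the axon guidance score was higher in GFP+ nuclei by 0.29, and the immediate early score differed by -0.08. Axon guidance and pan-neuronal scores were 7.98 and 9.18 in the GFP- library ES8, and 8.53 and 10.25 in ES2. A lower share of neurons in the GFP- sort could thus give the negative relation. The relative difference of immediate early genes was -0.54 at P7, -1.69 at P21 and -0.25 at P80, and at P21 it was -0.79 without the library ES16.

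The authors' deposited calls overlapped these to different degrees. At the authors' adjusted p under 0.05, 8707 genes were called over all ages, and 8193 of them (94.1%) were among the 8967 called here with limma, in the same direction. At P7 the authors called 4569, of which 2972 (65.0%) were among 3203. At P21 they called 2877, of which 2789 (96.9%) were among 6128, and at P80 4347, of which 4019 (92.5%) were among 5214, again in the same direction. The authors' log2 fold change of Pdyn was 6.36 over all ages and 7.03 at P7.

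Across ages in GFP+ nuclei the authors called 3331 genes, of which 1631 (49.0%) were among the 1786 called here in at least 1 of the 3 age comparisons. Their genes carry 1 of 4 cluster letters, and letters A and B are exchanged between the 2 deposited tables: 1374 genes are A in one and B in the other, 1185 the reverse, while 81 genes are C and 691 are D in both. With the letters of the table of clusters, mean centred log2 values at P7, P21 and P80 were -0.39, 0.10 and 0.32 in A, which held 6 immediate early genes, and 0.56, -0.23 and -0.38 in B, which held 11 immature neuron, 5 oligodendrocyte precursor and 5 astrocyte genes. They were -0.16, 0.61 and -0.29 in C, which held 4 oligodendrocyte genes, and 0.53, 0.16 and -0.65 in D, which held 10, with 5 oligodendrocyte precursor and 5 astrocyte genes. In A 46.3% of tested genes were higher and 14.7% lower in GFP+ than in GFP- nuclei. The shares were 26.5% and 42.4% in B, 18.5% and 51.9% in C, and 18.5% and 57.8% in D.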
